A study of Mus musculus with 3 samples.

How the data were processed

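ATRX ChIP-seq peak lists of 2 conditions were used, control (mCherry) and MICAL1-FL, in mouse primary neurons. Per the labels' protocols, neurons were taken from C57BL6/J embryos at E15.5 to E17.5, infected with lentivirus on day 5 in vitro, and profiled with an enzymatic ChIP kit and an antibody against ATRX, with input DNA as background and paired-end sequencing on a HiSeq instrument. The labels also name 1 input sample of control neurons, which was not analysed here. Groups were taken from the sample titles. Peak identifiers of the MICAL1-FL list begin with TBC_M2 and those of the control list with CTL. The title was followed, and this mismatch was left open.

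Per the submitters' processing notes, Bowtie 1.3.0, SAMtools 1.9, MACS 1.4.2 and ChIPseeker 1.26.2 were used, with no role or order stated. The calling threshold and the genome build are not given in the sources used here, nor is the program that wrote the lists, whose layout has a q-value and a summit per peak. There was 1 list per ChIP sample. The score of a peak, as deposited, was the whole part of 10 times its -log10 p, tested on every peak of both lists. The fold of a peak is a ratio over background made by the authors' peak caller. The -log10 p and -log10 q values are those of the authors' peak caller, with a largest p of 0.0498 in the control and 0.0496 in the MICAL1-FL list. The authors' summit offset gave the summit position.

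Depth was read from the values. Fold was taken as the ratio of pileup + 1 to background + 1, and p as the Poisson probability of a higher pileup. This gave pileups within 0.05 of a whole number for over 99.9% of peaks in both lists. It is an inference, as no label states it. The lowest background was 1.622 fragments in the control and 1.617 in the MICAL1-FL list, and 63.0% and 68.5% of peaks lay within 0.001 of it. Backgrounds above it moved in steps of 0.462 and 0.384, the best of sizes from 0.3 to 0.6, with 65.2% and 56.6% of them within 0.003 of a multiple. Read as input scaled to the ChIP library, this corresponds to 2.16 and 2.60 input fragments per ChIP fragment. If so, the lists were not called against the same relative input depth, and whether the same input served both is not given in the sources used here. Folds are therefore not compared between lists as a measure of change.

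The gene table was that of mouse GRCm38.p6, with 21887 protein-coding genes on the chromosomes. It has no strand, exons or sequence. The build was settled from the data, by scaffold names and by a sharp rise of summits at gene ends, and none of the table's coordinates are printed. Promoters, UTRs, exons, introns and sequence features had been planned and could not be told without strand, exons and a genome. In their place, chosen after the data were examined, genes were scored by a peak within 1 kb of either end, and gene lists by peaks within the gene and 5 kb on both sides. Genes said to hold a peak overlap it.

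Choices fixed before the data were examined were the groups, the overlap of at least 1 bp, 100 random placements within chromosomes, the 25 gene lists, the rule for named genes and the alternatives of threshold, overlap, chromosomes and window size. Added later were a shift of each peak by 50 to 500 kb, all alternatives with gene ends, the overlap between the strongest groups of both lists and the handling of ties. Chromosome and window ratios have exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals, at 95%. With 1 library per condition no test between conditions was possible. Gene lists were set beside 10000 random lists of equal size matched on 10 groups of gene length. Percentiles of peak density on the union of gene spans, and counting intervals for list ratios, were added after clustered families had been seen to share peaks. Peaks were ranked by -log10 p, and ties were put in random order after order by position had been seen to drop X chromosome peaks.

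Named genes followed the rule for data without a promoter annotation. It took the 10 peaks of each list with the highest fold and no peak of the other list within 3 kb, and the 10 shared peaks with the highest control fold. From each gene list it took up to 3 members with an end peak in 1 list alone and up to 2 with one in both, of which examples are given. Atrx, Daxx and Mical1 were always named. A peak and a window that these rules select are not reported here. Pgk1, the satellite stretches, the windows, the chromosome ends and members of the axon guidance list named by peak number were chosen after their values were seen.

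Steps were tested on simulated data. With 0, 5 and 20% of 105674 peaks planted as shared, 3.50, 8.36 and 22.9% overlapped, where 3.44, 8.27 and 22.8% were due. Pileups were recovered for 100% of 5000 simulated peaks. Of 200 gene lists of 36 genes, 7% fell outside the random range with no change planted, 64.5% with a change of 1.5 times and 98% with 2 times. For lists of 100 genes these were 3.5%, 98% and 100%. The software was Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.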

Results

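ATRX is a chromatin remodeller of the SWI/SNF family that is known to deposit histone H3.3 with its partner DAXX at telomeres and pericentromeric repeats. MICAL1 is a flavin monooxygenase known to oxidise actin filaments. ATRX-bound DNA was profiled by ChIP-seq in cultured neurons of C57BL6/J mouse embryos at E15.5 to E17.5, infected with lentivirus on day 5 in vitro and collected on day 14. Control neurons received mCherry and the others MICAL1-FL, and the question was whether ATRX occupancy differs between them. There was 1 ChIP library per condition, so no difference between conditions has a replicate check. Intervals are 95% exact binomial (Clopper-Pearson) intervals that cover counting error only. Folds and p- and q-values of single peaks are the authors' own and serve to describe and rank peaks within a list. Coordinates are those of the deposited lists. No label names the genome build, and chromosome and scaffold names and the gathering of peaks at gene ends fitted mouse GRCm38.

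The control list held 112153 peaks over 43.2 Mb and the MICAL1-FL list 105674 peaks over 40.3 Mb, with median widths of 334 and 332 bp. Peaks were shallow in both lists, with depth recovered from the authors' fold and p. The median peak was 5 ChIP fragments deep, and 83.3% of control and 85.8% of MICAL1-FL peaks were at most 6 fragments deep. The q-value was 1 for 95.8% and 96.9% of peaks, below 0.05 for 466 and 402, and 0.001 or less for 175 and 179. The last group is called strict peaks here. The lowest expected depth was 1.62 fragments in both lists. The autosomal ratio of MICAL1-FL to control peak numbers was 0.947 at 4 or more fragments, lowest at 9 or more (0.736, 0.688 to 0.787) and 0.877 at 12 or more (0.747 to 1.03). Peak identifiers in the list labelled MICAL1-FL begin with TBC_M2, which does not name MICAL1-FL. The group was taken from the sample labels, and every MICAL1-FL value here rests on that label.

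The tallest ATRX peaks of both libraries lay at the same places. The strongest peak by p-value covered chromosome 2 98666611 to 98667303 in the control list, with a depth of 42596 fragments and a fold of 3.002. The MICAL1-FL peak at this place was 43885 fragments deep with a fold of 3.51. Next in both lists came a peak at chromosome 9 35305262 to 35305576 in control coordinates, with folds of 3.10 and 3.55. The first assembled bases of chromosome 9, from 3000017 to 3038304, are known to hold major satellite repeats. They carried 25 strict control peaks with a median fold of 3.71 and 16 strict MICAL1-FL peaks with a median fold of 5.50. The lower number goes with wider calls, since 7 MICAL1-FL peaks overlapped 16 control peaks, the other 9 overlapped 1 each, and the lists covered 25796 and 31538 bp there. At 15 pairs of peaks with summits within 250 bp there, the median log2 ratio of depths was -0.0020. The unplaced scaffold JH584304 carried 23 and 25 strict peaks with median folds of 3.89 and 5.20. All scaffolds outside the chromosomes together held 28.0% of strict control peaks (21.5 to 35.3) and 33.5% of strict MICAL1-FL peaks (26.7 to 40.9). No repeat annotation was used, and depth at such places need not count single sites, since repeat copies collapsed into 1 reference stretch pile up reads in ChIP and input alike.

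Over their whole length the lists had few peaks in common. Of the control peaks, 7731 overlapped a MICAL1-FL peak by at least 1 bp, which is 6.89% (6.75 to 7.04). Of the MICAL1-FL peaks, 7717 overlapped a control peak, or 7.30% (7.15 to 7.46). Random placement of the other list within its chromosomes gave means of 3.27% and 3.46% over 100 placements, so the overlap was 2.11 times the random value in both directions. Shifting each peak of the other list by 50 to 500 kb, which keeps regional density, gave 3.59% and 3.80%. Sharing was higher among strong peaks. With each list ranked by p-value and split into 10 equal groups, 12.2% of control peaks (11.6 to 12.8) and 13.3% of MICAL1-FL peaks (12.7 to 13.97) were shared in the strongest group, against 4.90% to 8.42% and 4.58% to 8.13% in the others. Among strict peaks, 139 of 175 control peaks (79.4%, 72.7 to 85.2) and 132 of 179 MICAL1-FL peaks (73.7%, 66.7 to 80.0) overlapped a peak of the other list. Scaffolds and the chromosome 9 stretch raised this share, and on the rest of the chromosomes it was 65 of 101 (64.4%, 54.2 to 73.6) and 69 of 103 (67.0%, 57.0 to 75.9). High input remained there too. Of the 39 pairs there that were strict in both lists with summits within 250 bp, most had control backgrounds far above the lowest of 1.62. These reached 14190 fragments, at chromosome 2 98666611. Exceptions include chromosome 7 118291548 (1.62) and chromosome X 170674044 (5.55). The shares depended on what counts as shared: they were 17.7% and 18.7% with peaks up to 1 kb apart, 4.50% and 4.77% with summits within 250 bp, 3.94% and 3.73% between the strongest 10000 peaks of each list, and 63.4% and 52.5% between the strict peaks of both. Random placement was run only for the overlap of at least 1 bp between the full lists. These other shares have no chance level here, so their sizes do not show which definition exceeds chance the most.

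**Figure D1:**
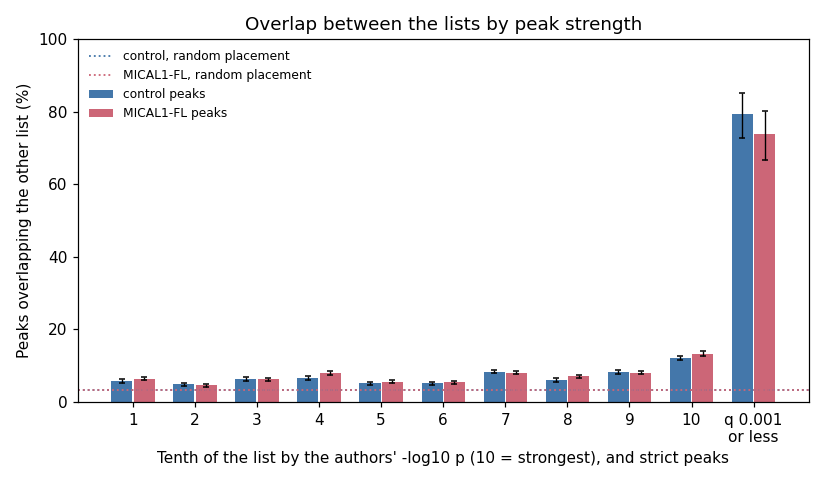
Percent of peaks of each list (blue control, red MICAL1-FL) that overlap the other list by at least 1 bp, for 10 equal groups of the list ranked by the authors' -log10 p and for peaks with a q-value of 0.001 or less. Bars start at 0, error bars are 95% exact binomial intervals and dotted lines are the random placement means of 3.27% and 3.46%, with the strongest groups at 12.2% and 13.3% and the strict peaks at 79.4% and 73.7%.

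The X chromosome had fewer peaks per Mb than any autosome in both lists, and fewer in MICAL1-FL neurons than in control neurons. Its density was 10.4 peaks per Mb in the control list and 6.58 in the MICAL1-FL list, where autosomes together had 45.9 and 43.4. The X chromosome held 1745 control and 1103 MICAL1-FL peaks, a ratio of 0.632 (0.586 to 0.682). The ratio was 0.947 over all autosomes and ranged from 0.883 on chromosome 17 to 1.01 on chromosome 16. The Y chromosome held 73 and 58 peaks, a ratio of 0.795 (0.553 to 1.14). Relative to autosomes, the X ratio was 0.668 (0.619 to 0.720). Among the strongest 10000 peaks of each list it was 0.785 (0.5996 to 1.03), with tied p-values in random order. Over 100 random orders it lay between 0.703 and 0.837, with intervals that include 1 in 34 of them, and it was 1.56 with ties kept from chromosome 1 on, an order that drops X chromosome peaks of the control list.

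**Figure D2:**
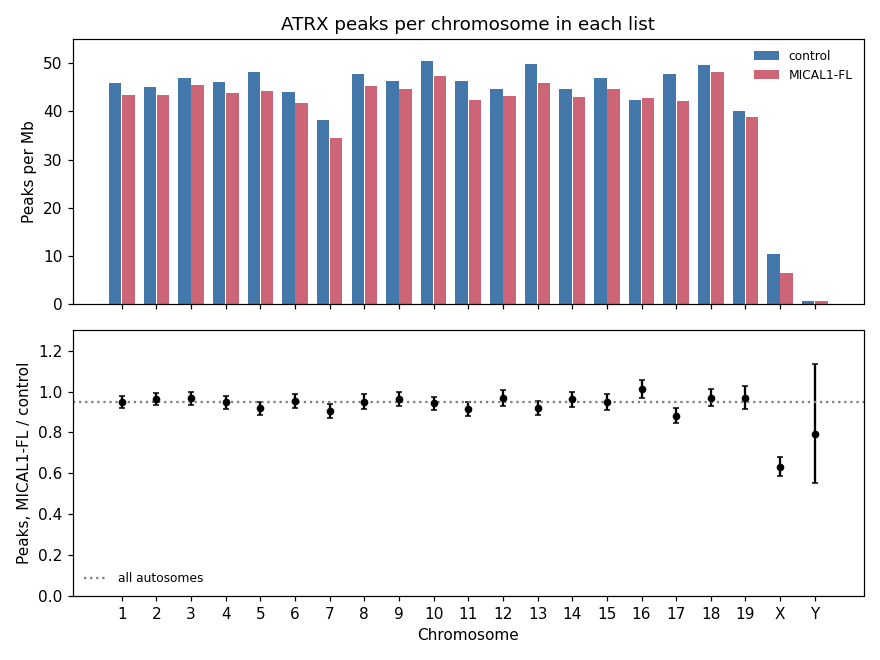
Peaks per Mb of each chromosome in the control (blue) and MICAL1-FL (red) lists (upper panel), and ratio of MICAL1-FL to control peak numbers with 95% exact conditional binomial intervals and, dotted, the ratio of 0.947 over all autosomes (lower panel). The X chromosome stands at 0.632, below every autosome.

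Along the chromosomes, regional peak numbers of the lists went together. Across 1 Mb windows of the autosomes, Pearson's r was 0.785 and Spearman's rho 0.763 (windows are neighbours on the same chromosomes, not independent replicates). Of 2530 windows with at least 10 peaks, 190 (7.51%, 6.51 to 8.61) had a ratio whose counting interval left out that of all windows, 102 of them above it and 88 below, where counting error alone gives at most 5%. With 5 Mb windows the share outside was 15.1%. Windows are named by the smallest exact binomial probability, a choice made after the values were seen. The first of them was chromosome 8 from 20000001 to 21000000, with 16 control and 58 MICAL1-FL peaks (ratio 3.62, 2.06 to 6.76), which holds Defb33 of the beta-defensin family. Chromosome 18 from 55000001 to 56000000, with no annotated protein-coding gene, had 51 and 90 peaks. Lower in the MICAL1-FL list was chromosome 5 from 105000001 to 106000000, with 95 and 46 peaks (ratio 0.484, 0.333 to 0.696), where the interferon-induced GTPase genes Gbp4, Gbp6, Gbp8, Gbp9 and Gbp10 lie. The window on chromosome 9 from 70000001 to 71000000, which holds the sheddase gene Adam10 and the myosin gene Myo1e, had 70 and 30 peaks.

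ATRX peaks were gathered at the ends of protein-coding genes in both lists. The gene table used here has no strand, so the start and the end of a gene cannot be told apart. Summits within 250 bp of a gene end were 2.11 times as many in the control list, and 2.56 times as many in the MICAL1-FL list, as in windows of equal size at distances of 5 to 10 kb. Summits within 1 kb of a gene end made up 5.45% of control peaks (5.32 to 5.59) and 5.42% of MICAL1-FL peaks (5.28 to 5.55), where shifted peaks gave 3.05% and 2.84%. A further 39.0% and 38.5% lay elsewhere in protein-coding genes, 8.99% and 9.11% in other annotated genes, and 46.5% and 47.0% outside annotated genes. Of 21887 protein-coding genes, 6418 had a control peak and 6114 a MICAL1-FL peak within 1 kb of an end. Both lists had such a peak at 2686 genes, 1.498 times the 1793 expected of independent lists, the control list alone at 3732 and the MICAL1-FL list alone at 3428. At a gene with an end peak in both lists, the peaks need not overlap or lie at the same end. These 3 counts were 5469, 4380 and 3903 with ends within 3 kb, and 1678, 3097 and 2930 with ends within 500 bp. With strict peaks, 1 gene had an end peak in both lists, 14 in the control list alone and 5 in the MICAL1-FL list alone, and 10.3% of strict control and 4.20% of strict MICAL1-FL summits lay within 1 kb of an end. A peak in 1 list alone does not show a difference at that gene, since most peaks are a few fragments deep.

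**Figure D3:**
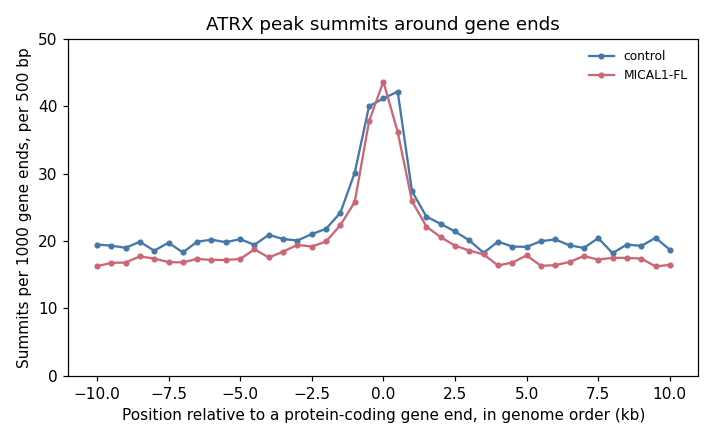
Peak summits per 1000 protein-coding gene ends in windows of 500 bp, by position relative to the end in genome order (kb), in the control (blue) and MICAL1-FL (red) lists. At the gene end the curves reach 41.2 and 43.7 summits per 1000 ends, from 19.5 and 16.3 at 10 kb before it.

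Gene groups differed widely in how many ATRX peaks they carried. The clustered protocadherins, neuronal adhesion molecules in tandem arrays on chromosome 18, had 169 control and 129 MICAL1-FL peaks per Mb of gene and 5 kb flank, against medians of 50.2 and 47.5 for random gene lists of equal length. The protocadherins cover 0.661 Mb in neighbouring arrays, while random lists drew genes from across the genome. Activity-regulated genes, which neurons induce after firing, had 101 and 82.2 peaks per Mb (random medians 43.5 and 38.8), at the 99.99 and 99.97 percentiles of 10000 random lists. An end peak was present at 17 of these 32 genes in the control list and 18 in the MICAL1-FL list. Among them Gadd45g had one in both lists (folds 3.81 and 3.32), Nr4a1 in the control list alone (fold 3.81) and Bdnf in the MICAL1-FL list alone (fold 3.44). Olfactory receptors had 17.7 and 13.4 peaks per Mb and vomeronasal receptors 9.59 and 8.74, below all 10000 random lists in both libraries. No peak of either list lay at 800 of 1106 and 283 of 353 of these genes. Random lists were matched on gene length alone, and how well reads map in these families was not measured. Low numbers there need not mean little ATRX. High numbers in other groups need not mean more ATRX either, since traits other than length were not matched and most peaks were a few fragments deep. Clustered histone genes had 43.9 and 49.0 peaks per Mb, at the 98.3 and 99.9 percentiles of random lists of equally short genes. Neuronal identity transcription factors had an end peak at 22 and 17 of 31 genes, against 35.1% and 33.3% of random genes, with peaks in both lists at Foxp2 (folds 3.05 and 3.82) and Sox5. The highest end peaks of the lists did not overlap at Foxp2 or Sox5.

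Of the 25 gene lists, 3 had a MICAL1-FL to control ratio outside the middle 95% of random lists, where 1.25 are expected by chance. Axon guidance and dendrite growth genes had 530 control and 636 MICAL1-FL peaks, a log2 ratio 0.37 above that of all protein-coding genes (counting interval 0.21 to 0.54), at the 99.9 percentile. Their density was 41.6 control peaks per Mb (random median 50.5, 6.12 percentile) and 49.9 MICAL1-FL peaks per Mb (random median 47.9, 64.4 percentile), so the control value was the one farther from random lists. Of its 36 members, 26 had a ratio above that of all genes. The log2 ratio of all genes was -0.11, so a member with equal counts lies above it. Such shares varied in lists inside the random range, with 18 of 26 glutamate receptors and 12 of 30 voltage-gated ion channels. Leaving out any single axon guidance gene kept the log2 value between 0.34 and 0.41. Members picked after their values were seen include the Slit receptors Robo1 (27 control and 38 MICAL1-FL peaks) and Robo2 (42 and 59), and the netrin receptors Dcc (32 and 43) and Unc5c (13 and 28). In the other direction were the ephrin receptor Ephb1 (32 and 24) and the semaphorin Sema3d (9 and 3). Of the members, Unc5c alone had a counting interval for its own ratio that excludes 1. The intervals of Robo2 (0.930 to 2.14) and Nrp1 (0.931 to 42.8) include 1 but narrowly exclude the ratio of all genes. Clustered protocadherins (112 and 85 peaks, log2 -0.29) and olfactory receptors (223 and 169, log2 -0.29) lay below the random range. Their own counting intervals, -0.71 to 0.13 and -0.59 to 0.01, include the ratio of all genes, and neighbouring members share peaks.

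The other lists lay inside the random range of the ratio. Of them, presynaptic release (0.06 to 0.46) and keratin genes (-1.14 to -0.01) had counting intervals that exclude the ratio of all genes. Among the synaptic lists the log2 ratio relative to all genes was 0.14 for glutamate receptors, 0.18 for GABA and glycine receptors, -0.10 for postsynaptic scaffolds and adhesion, 0.26 for presynaptic release and -0.13 for voltage-gated ion channels. It was 0.10 for neuronal identity transcription factors and -0.18 for activity-regulated genes. The ATRX and H3.3 heterochromatin factors had 0.19, imprinted genes 0.14, MICAL family and actin regulators -0.14, and zinc finger genes -0.07. Markers of other cell types that such a culture could hold had 0.41 (astrocytes), 0.30 (microglia and macrophages) and -0.05 (oligodendrocyte lineage). Ribosomal protein genes had -0.05, oxidative phosphorylation genes 0.39, clustered histone genes 0.27, vomeronasal receptors -0.02, keratin genes -0.56, Hox genes -0.34, liver and muscle genes -0.24, and the alpha and beta globin loci -0.97 on 9 and 4 peaks. The share of genes with an end peak in the MICAL1-FL list less that in the control list lay outside the middle 95% of random lists for 2 gene lists, where 1.25 are expected by chance. These were the globin loci (-42.9 percentage points, 0.145 percentile) and the Hox genes (-23.1 percentage points, 0.645 percentile). Random lists drew genes from across the genome, while both of these lists lie in clusters whose members can share an end peak. Clustered lists may spread more widely than random ones, so the percentiles and the 1.25 may overstate how unusual they are. At the globin loci, whose alpha genes are known to need ATRX for full expression, 6 of 14 genes had an end peak in the control list and 0 in the MICAL1-FL list, where random genes gave 16.1% and 14.8% (99.1 and 5.005 percentiles). Among them were Rhbdf1 (fold 4.96) and Mpg (fold 3.05), which each had 1 MICAL1-FL peak elsewhere in the gene. Rhbdf1 and Mpg are neighbours of the alpha-globin genes and not globin genes themselves. Within the gene and 5 kb on both sides, Hba-a1 had 0 peaks in each list, and Hba-a2 had 1 control and 0 MICAL1-FL peaks. The count therefore does not show a loss at the alpha-globin genes. Of 39 Hox genes, 15 had one in the control list and 6 in the MICAL1-FL list, from 16 and 4 distinct peaks, where random genes gave 27.2% and 25.6% (93.5 and 6.63 percentiles, each inside the middle 95%), with Hoxd10 (fold 3.90) and Hoxb7 (fold 3.81) in the control list alone.

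**Figure D4:**
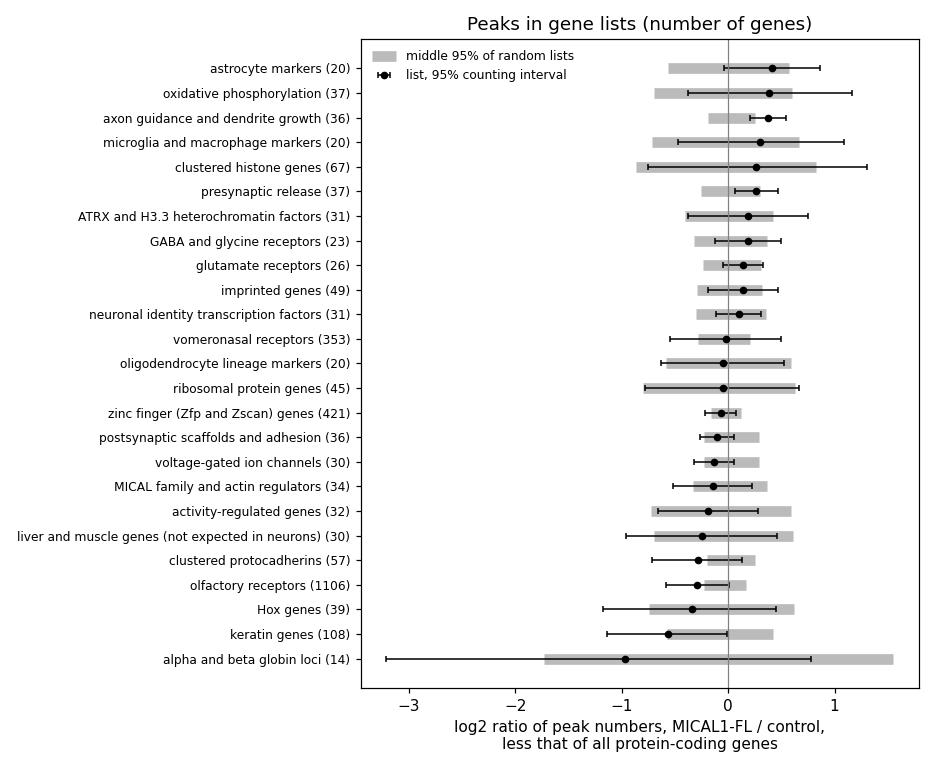
Log2 ratio of MICAL1-FL to control peak numbers in each gene list, less that of all protein-coding genes, with 95% counting intervals (points and bars) and the middle 95% of 10000 random lists matched on gene length (grey), with numbers of genes in brackets. Axon guidance and dendrite growth stands at 0.37, outside the random range of -0.19 to 0.25.

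Among control peaks with no MICAL1-FL peak within 3 kb (74150 peaks), those with the highest fold lay mostly in or beside genes. The first was at chromosome 18 58659030 to 58659413 beside Isoc1, with a fold of 6.10 and a -log10 q of 5.98. The second was at chromosome 3 121426454 to 121427357 in the calponin gene Cnn3 (fold 5.96). Others were in Eif1, a translation initiation factor (chromosome 11 100319971 to 100320340, fold 5.34), Tmem163 (fold 5.26) and Gm31323 (fold 5.26). Paip1, Tead1 and an intergenic site on chromosome 16 each had a fold of 4.96, and Ttc21b had 4.61. Of the 10 peaks of this set, 8 overlapped an annotated gene.

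Among MICAL1-FL peaks with no control peak within 3 kb (68235 peaks), the highest fold was in Gphn, which encodes the inhibitory postsynaptic scaffold gephyrin. This peak, at chromosome 12 78350869 to 78351180, had a fold of 8.33, a -log10 q of 22.7 and a depth of 41 fragments. Next were Gm46595 (chromosome 17 70963658 to 70963929, fold 5.55), a site at chromosome 4 3068746 to 3069653 (fold 5.48) and Gm30821 (fold 5.35). Gm18728 and Grid2ip, which encodes the glutamate receptor partner delphilin, each had a fold of 4.97. Gm7592 had 4.84, Spag17 4.76, an intergenic site on chromosome 13 4.67 and Armc2 4.59. Here too 8 of the 10 peaks overlapped an annotated gene. The highest fold of the whole MICAL1-FL list, 22.2, was in Pgk1 at chromosome X 106186723 to 106187340, with a -log10 p of 67.0 and a depth of 57 fragments. This peak is named after its value was seen, since weak control peaks within 3 kb keep it out of the set above. The nearer of these control peaks, 106186201 to 106186500, had a fold of 1.91 and a depth of 4 fragments.

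The 4 shared peaks with the highest control fold lay on unplaced sequence and near the ends of the sex chromosomes. The first was on scaffold 4_GL456216_random from 31761 to 35879, with folds of 7.07 in control and 6.82 in MICAL1-FL neurons. The second was at chromosome X 170674044 to 170677931 in Asmt, the pseudoautosomal gene for the last enzyme of melatonin synthesis, with folds of 7.02 and 6.36. Chromosome Y peaks at 90819525 to 90819887 and 90734615 to 90735388 followed, with folds of 6.40 and 6.31 in control and 3.06 and 3.17 in MICAL1-FL neurons. Gm21814 on chromosome 6 had folds of 6.10 and 3.82, and B3gnt2 on chromosome 11 had 4.96 and 2.68. Side by side, folds of a pair do not measure a change, because each is relative to its own list's background. At Gm21814 and B3gnt2 the backgrounds were nearly equal, at 1.62 in both lists. All these pairs were picked for a high control fold, which by itself favours a lower MICAL1-FL fold. Among strict shared peaks the MICAL1-FL fold was higher in 75 of 86 pairs.

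The genes behind the experiment carried few peaks. Atrx itself had 1 control peak inside the gene, and 1 MICAL1-FL peak within 1 kb of an end with a fold of 2.29. Mical1 had 1 peak inside the gene in each list and none at its ends, and Daxx had none in either list. Among heterochromatin factors, Dnmt3b and Hira had end peaks in both lists, Smarca5 in the control list alone and Setdb1, a histone H3 lysine methyltransferase, in the MICAL1-FL list alone. These folds were between 2.29 and 3.06, all with a q-value of 1. Among receptor and guidance genes, Grid1 had end peaks in both lists (folds 4.17 and 3.77), Efna5 in both (folds 4.58 and 2.68), Gria1 in the control list alone (fold 3.07) and Gabrb2 in the MICAL1-FL list alone (fold 3.77). The highest end peaks of the lists overlapped at Grid1 but not at Efna5, Dnmt3b or Hira. Those of Hira began at chromosome 16 18877209 in the control list and 18971179 in the MICAL1-FL list.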

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

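The tests with gene ends, with shifted peaks, with counting intervals of gene lists, with other handling of tied p-values and between the strongest 10% of both lists were chosen after the data were seen. No paired analysis was possible because each condition had 1 library. Of 58 alternatives over 17 results, 22 stayed within the counting interval or 1.5 times the count, 35 moved beyond it and 1 turned direction. A planned comparison of the strongest 10% with the full other list is the reported value itself and was not counted. Where no construction is named, the cause was not tested. With a q-value of 0.001 or less there were 175 control and 179 MICAL1-FL peaks, sharing was 63.4% and 52.5%, end peaks were at 1 gene in both lists and 14 and 5 genes in 1 list alone, and 10.3% and 4.20% of summits lay near gene ends. With a fold of at least 1.5 times the list median 3298 and 889 peaks were left. This contrast comes from rounding, since 2072 control and 1679 MICAL1-FL peaks lay on the limit itself and only the control ones passed it, with 1226 and 889 peaks clearly above. Sharing was 4.75% and 5.01% with at least 50% of the shorter peak, 4.50% and 4.77% with summits within 250 bp, and 17.7% and 18.7% within 1 kb, which follows from stricter and looser definitions. With lists of equal length the MICAL1-FL share was 6.93%. Between the strongest 10000 peaks sharing was 3.94% and 3.73%, and end peaks were at 164 genes in both lists and 961 and 979 in 1 alone, since fewer peaks enter. Between the strongest groups of both lists it was 3.83% and 3.89%. Random placement and shifts were run only for the overlap of at least 1 bp between the full lists, so these alternatives have no chance level. Against shifted peaks the overlap was 1.92 times in both directions. With ends within 3 kb 5469 genes had a peak in both lists, 10.8% and 10.7% of summits lay near an end, and the difference in end peak share lay outside the random range for 4 gene lists, the globin loci and Hox genes as before, protocadherins and imprinted genes. With ends within 500 bp there were 1678 such genes. With 5 Mb windows 15.1% lay outside the counting interval, where counting error alone gives at most 5%. Larger counts have narrower intervals, so smaller regional differences between the libraries fall outside them. The X chromosome ratio relative to autosomes was 0.785 for the strongest 10000 peaks with ties in random order, 0.756 with all ties kept, 0.644 with ties kept from the last chromosome back and 1.56 with ties kept from the first chromosome on. The last value follows from its construction, because 6781 control peaks shared the p-value at the limit and those on the X chromosome were dropped. The number of gene lists outside the random range was 3 under each alternative. With the gene span alone keratin genes took the place of olfactory receptors, and axon guidance and protocadherins were outside there and with equal numbers. Whole-peak sequence features and promoter windows were not run, for want of a genome and strand. Depth limits all of this, as the median peak was 5 fragments deep.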

Other observations

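All tests of explanations in this part were chosen after the results they address had been seen.

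The last 1 kb of some chromosomes, up to the end of the farthest peak in either list, held deep control peaks. On chromosome 7 the strongest there was 81 fragments deep (fold 3.93), on chromosome 14 82 (fold 3.03) and on chromosome 18 86 (fold 3.03), with no MICAL1-FL peak in the same 1 kb. Backgrounds at these peaks were 19.9, 26.4 and 27.7 fragments, far above the lowest of 1.62, so input was high there too. On chromosome 2 both lists had a peak there, 104 and 114 fragments deep. Both also had one on chromosomes 4 (177 and 116), 6 (15 and 9), 10 (34 and 26) and 15 (8 and 5). On chromosome 4 the fold was 1.73 in the control and 2.71 in the MICAL1-FL list. Chromosomes 1, 12 and X had a control peak alone, 36, 77 and 46 fragments deep. On chromosomes 8, 9, 11, 13 and 17 the strongest was a control peak of 5 fragments, and on chromosomes 5 and 19 a MICAL1-FL peak of 4. These ends are set by the farthest peak itself, so peak numbers there were not compared between the lists or with chance.

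At strict peaks that both lists shared, the authors' fold was higher in the MICAL1-FL list. In 86 pairs with summits within 250 bp it was higher in 75, with a median log2 ratio of 0.52. The tables argue against more ATRX fragments at these peaks, since the median log2 ratio of pileups was -0.081 (quartiles -0.23 to 0.02). The lowest backgrounds differed by a log2 ratio of -0.0046, which gives no sign of a deeper ChIP library. With input scaled to the ChIP library, depth would move pileup and background alike, so this says little about the fold. A lower input background could account for the higher fold. The median log2 ratio of backgrounds was -0.61 and 83 pairs had a lower one. Background was computed from fold and pileup, however. A lower background at nearly equal pileup restates the higher fold and is not a separate test. No input of MICAL1-FL neurons is named in the labels. If background steps are read as scaled input fragments, 1 input used for both lists would shift backgrounds by the log2 ratio of the steps, -0.27. The median of -0.61 (quartiles -0.77 to -0.47) argues against 1 shared input at these pairs. A gain relative to the MICAL1-FL culture's own input is left open.

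The X chromosome ratio of 0.632 (0.586 to 0.682) lay below every autosome. A lower yield of tall peaks is argued against as the whole cause, since autosomal peaks thinned to about the X chromosome's density, at 7 or more fragments, had a ratio of 0.804 (0.787 to 0.822). More male embryos in the MICAL1-FL culture may lower it, and the Y chromosome ratio of 0.795 (0.553 to 1.14) does not decide. Less ATRX on the X chromosome may also do so, and with 17 of 18 windows of 10 Mb below the autosomal ratio (range 0.418 to 1.12) it cannot be told apart from a change in copy number. The ratio was 0.576 (0.527 to 0.629) up to 130 Mb and 0.844 (0.723 to 0.985) beyond, a split chosen after the windows were seen, and 6.62% of 10000 draws with an even ratio were as uneven over the 18 windows, so an even loss is not excluded.

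The Pgk1 peak of the MICAL1-FL list, with a fold of 22.2, stood apart from the next highest fold of 8.33. A low background is argued against, since its 57 fragments compare with at most 15 at other peaks on the lowest background. ATRX at active housekeeping genes is argued against too, as the highest fold at the ends of ribosomal protein and oxidative phosphorylation genes was 3.82. Pgk1 promoters are commonly used in lentiviral vectors, and vector DNA that carries the Pgk1 promoter may give such a peak. Control neurons were infected with lentivirus too, and control peaks within 3 kb were only 4 and 5 fragments deep. Vector DNA would therefore have to differ between the cultures in this promoter or in amount. The background at the peak was 1.617 fragments, the lowest of the list, so the input used showed no excess of DNA there. This does not decide on vector DNA, because which input served this list is not given. Input of control neurons, the only one the labels name, could not show vector DNA of the MICAL1-FL culture alone. The number of peaks in Mical1, 1 in each list, does not decide on vector DNA either, because the vector is not described in the labels.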
